A study of Arabidopsis thaliana with 8 samples.

How the data were processed

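The series holds 8 Affymetrix ATH1 arrays of Arabidopsis thaliana Col-0 grown on soil, 2 at each of 4 times: before cold (0 h, the control) and after 1 h, 24 h and 7 d at 4 °C. Each array was grouped by the time named in its labels, and its replicate number was taken from its title. The deposited values are MAS5 signal intensities on a linear scale, with MAS5 named in the submitters' processing notes and its version not given in the sources used here. MAS5 summarises the perfect-match and mismatch probes of a probe set into 1 signal. In the values themselves, the mean after trimming 2% of the probe sets at each end was 100 on every array, which is the scaling that was kept. Detection calls, scanner images and scan dates were not used here, so no scan batch was tested. The number of arrays, 2 per time, limits the precision of every value: the median standard error of a log2 fold change was 0.19.

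Of 22810 probe sets, 64 control probe sets were left out. The platform annotation named 1 gene for 13513 of the others, several genes for 503 and none for 8730. The genes of these last probe sets are unnamed here, and no gene was named from a probe set with several. Of the probe sets naming 1 gene, 88.3% gave only a locus tag, and such genes are called by that tag. Locus tags came from RefSeq's table for the assembly TAIR10.1, used for names alone. Where several probe sets named a gene, the one with the highest mean stood for it in gene lists.

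The intensities were used as log2(signal + 6.07), where the pseudocount is the 20th percentile of the table, and a fold change is on that scale, which understates the change of weakly expressed genes. Probe sets at or above their array's 40th percentile on at least 2 arrays were tested, 14756 in all; 8045 of them named 1 gene, 288 several and 6423 none. A mean per time was fitted over all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), leaving 4 residual degrees of freedom per probe set. The comparisons were 1 h, 24 h and 7 d against control, 24 h against 1 h and 7 d against 24 h, with a moderated F test over all times. A probe set passed at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p of a gene comes from this limma fit. The tests were two-sided. The fit, its filter, the pseudocount and the rule for naming genes were chosen before the data were examined, as were the alternatives except 3.

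Genes were named by that rule. For each comparison with control it took the 8 largest changes in each direction among probe sets that passed, that named 1 gene, and whose 2 cold arrays lay on the same side of both control arrays. From each gene list that passed its test or had at least 3 members past the threshold, it took up to 3 members with the smallest adjusted p. Cold marker genes and markers of other organs that passed were added, and for 24 h against 1 h and 7 d against 24 h the 5 largest changes in each direction by the same criteria. Of the cold markers, COR15A alone was named by a tested probe set, and the others are not reported here. Some genes that the rule took are described as part of their group.

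A total of 24 gene lists with 392 genes were also fixed before the data were examined. The annotation named 56 of those genes, and 9 lists had the minimum of 3 tested members. After the names in the annotation were seen, and before any difference was computed, 23 lists were added from those names, of which 21 were tested. Lists were tested with camera in limma at a preset correlation between genes of 0.01, which compares a list with all other probe sets. Adjustment was over the lists and 5 comparisons, separately for the lists fixed first (45 tests) and those added (105 tests). Each test was repeated with the correlation estimated from these arrays, and with fry, which asks whether a list's genes move, on balance, one way. At the preset correlation 34 of 150 tests passed. With the estimated correlation 0 passed in camera, and 7 of the 150 had an unadjusted p under 0.05. That version rests on the 4 residual degrees of freedom, so it had little power here. It gave an adjusted p of 0.442 even to the COR and CBF-target genes at 24 h, all 6 of which passed singly. Failing it is therefore weak evidence against a list. By fry, 17 of the 34 passed.

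The limma step was tested on simulated data for 24 h against control over 14756 probe sets. It recovered 7.46% of 67 changes of 1.5-fold, 38.8% of 67 changes of 2-fold and 80.3% of 66 changes of 4-fold, and 3 of its 87 calls were false (3.45%). Far fewer probe sets were changed there than the 3873 that passed at 24 h in the data, and they varied independently. These shares therefore do not carry over to the real comparison. In the simulated test of camera for the same comparison, a list of 20 genes shifted by 0.5 on the log2 scale was called, and 0 of 20 unshifted lists were. The simulated genes varied independently, so this does not show how often camera calls lists of correlated genes falsely.

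Nothing in the labels states that the arrays of a time came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The titles number the arrays Rep1 and Rep2 at each time, and no label says that a number marks a shared batch or day. The difference between replicate 1 and replicate 2, taken across the tested probe sets, correlated between times with r from 0.16 to 0.36 over the 6 pairs of times. Every value was above 0.1, so comparisons of single arrays took arrays of the same number as pairs. This rests on the correlation alone, and the counts from the fit with the replicate number as a block had been printed alongside it. The fit without the block was kept, as chosen beforehand, so its p-values take no account of any pairing. The blocked value stands beside a result where it changed the call or moved a count by more than 1.5 times.

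The alternatives were quantile normalization, centring on each array's median, a smaller and a larger pseudocount, no filter and a 60th percentile filter, eBayes without the trend, a 2-fold minimum, a fit of the 2 times compared alone, the replicate block, and leaving out each array in turn. For gene lists they also included the estimated correlation, fry and the mean over a gene's probe sets. Added after the data were seen were the fit of the 2 times alone for single genes, and the correlations between times without 1 array and with separate control arrays. Python 3.11.15 with matplotlib 3.10.9 drew the figures.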

Results

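Transcript levels were measured in the above-ground parts of soil-grown Arabidopsis thaliana Col-0, the common laboratory accession, before and during growth at 4 °C. The labels give an age of 18 d at every time, but also 4 d of stratification and 10 d at 22 °C, so the age at harvest is unclear. Growth was in continuous light of 100 µmol m⁻² s⁻¹. In the cold the light was about 25 µmol m⁻² s⁻¹, so every comparison of cold with control also compared dimmer with brighter light. Total RNA was labelled with biotin and hybridised to 8 ATH1 arrays, 2 for the control at 0 h and 2 each for 1 h, 24 h and 7 d in the cold. Warm plants harvested at 1 h, 24 h or 7 d were not analysed here, so time and plant age were not separated from cold. Median signals ranged from 32.8 to 37.7 over the arrays, and the highest signal of an array from 5814 to 9346. Replicate arrays correlated with r from 0.96 to 0.97 across probe sets, and arrays of different times with r from 0.89 to 0.97; probe sets are not independent replicates. Of 14756 probe sets tested, 4412 (29.9%) differed between any of the 4 times by limma's F test, and 1849 of these changed at least 2-fold in a comparison with control. Leaving out 1 array lowered this count to 2782 without 24 h replicate 1 and to 2543 without 24 h replicate 2.

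After 1 h at 4 °C, the largest rises among named genes were those of a small set of rapidly responding genes, while the cold marker COR15A had not passed. Of 21 listed CBF and early cold transcription factors 1 was tested, so the early cold genes as a group could not be judged. CML38, which encodes a calmodulin-like calcium sensor, rose 15.2-fold (log2 3.93 ± 0.44 SE, adjusted p = 0.00406, n = 2 arrays per time), from a signal of 9.89 ± 7.67 (SD) to 223 ± 25.2. STZ, a zinc-finger transcription factor, rose 12.9-fold to a signal of 1231 ± 137 (log2 3.69 ± 0.50, adjusted p = 0.0102). PUB19, a U-box ubiquitin ligase, rose 5.11-fold (log2 2.35 ± 0.27, adjusted p = 0.00472). The plastid-encoded psbA, the gene of the D1 protein of photosystem II, was 2.82-fold lower (SE 0.19 on the log2 scale, adjusted p = 0.00669). The plastid-encoded psbN was 3.51-fold lower (-1.81 ± 0.25, adjusted p = 0.0115).

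In all, 128 probe sets were higher and 6 lower at 1 h, and 121 and 4 of these changed at least 2-fold. Of the higher, 60 named 1 gene, 66 none and 2 several, and the largest rise, 5.61 on the log2 scale, belonged to an unnamed probe set. AT3G04640 rose 13.0-fold (3.70 ± 0.29, adjusted p = 0.000804) and AT4G29780 13.5-fold (3.75 ± 0.39, adjusted p = 0.00325). AT1G33760 rose by 3.92 ± 0.45 on the log2 scale, AT5G52050 by 3.57 ± 0.51, AT2G41640 by 3.24 ± 0.50 and AT2G27080 by 3.08 ± 0.36. The lower genes besides psbA and psbN were AT2G31150, AT3G26510, AT1G36730 and AT1G77840, with log2 changes from -1.35 to -0.74 and adjusted p from 0.0158 to 0.0447. Their calls ended without any 1 of the control and 1 h arrays. Each call also ended with the 2 times alone (adjusted p from 0.0531 to 0.101). With no filter the adjusted p was 0.0707 for AT3G26510, 0.0577 for AT1G77840 and 0.0886 for AT2G31150. Without the variance trend it was 0.0934 for AT3G26510 and 0.0859 for AT1G77840. For AT2G31150 it was 0.0721 with quantile normalization and 0.0507 with the smaller pseudocount. COR15A, whose protein protects chloroplast membranes in the cold, changed by -0.35 ± 0.29 (adjusted p = 0.939). The 6 tested COR and CBF-target genes, of which it is 1, had a median of 0.31, and their list did not pass camera at 1 h. The number of higher probe sets was 47 without control replicate 1, 34 without 1 h replicate 1 and 68 without 1 h replicate 2, and 215 with the replicate number as a block. The number of lower ones was 1 without control replicate 1, 3 without 1 h replicate 1 and 3 without either 24 h array. By limma it was 0 without control replicate 2 or without 1 h replicate 2, where 432 and 292 had an unadjusted p under 0.05.

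Of the named calls at 1 h, 2 of 15 held without each array in turn, those of AT3G04640 and AT4G29780. Without 1 h replicate 1 the adjusted p became 0.0675 for CML38, 0.106 for STZ, 0.173 for AT1G33760, 0.194 for AT5G52050, 0.245 for AT2G41640 and 0.0721 for AT2G27080. Without 1 h replicate 2 it was 0.0640 for STZ, 0.136 for AT2G41640, 0.0766 for AT2G27080, 0.0536 for psbA and 0.0696 for psbN. Without control replicate 1 it was 0.102 for STZ, 0.0571 for PUB19, 0.0856 for AT5G52050, 0.118 for AT2G41640, 0.0536 for AT2G27080 and 0.0860 for psbN. Without control replicate 2 it was 0.0845 for AT5G52050, 0.0577 for psbA and 0.0875 for psbN. With the smaller pseudocount the log2 change was 5.35 for AT1G33760 (adjusted p = 0.100) and 3.87 for AT2G41640 (adjusted p = 0.0801), and with the 60th percentile filter the adjusted p of AT1G33760 was 0.0547.

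Grouped by gene list, the touch and calmodulin-like genes, a list fixed beforehand, were higher at 1 h. Of the 3 tested members CML38 passed over all probe sets, and 3 did when adjusted over the list alone. The others were AT3G01830 at 2.05 ± 0.70 (adjusted p = 0.509) and CML37 at 1.93 ± 0.50 (adjusted p = 0.233). The list's camera test gave an adjusted p of 2.5e-06, but adjusted p = 0.442 with an estimated correlation. Its median of 2.05 was 1.36 without control replicate 1. The overlapping list of calmodulin-like proteins had 1 of 7 members higher and a median of 0.66 (adjusted p = 0.000568, and adjusted p = 0.811 with an estimated correlation). That median was 1.08 without control replicate 1 and 0.43 without 1 h replicate 2. Plant U-box ubiquitin ligases had PUB19 higher and 6 of 7 members not passing (camera adjusted p = 0.00401; adjusted p = 0.811 with an estimated correlation). Among these PUB25 stood at 0.90 ± 0.30 (adjusted p = 0.506) and PUB23 at 2.14 ± 0.41 (adjusted p = 0.0613). The adjusted p of PUB23 became 0.0362 with the replicate block, 0.0252 with the 2 times alone and 0.0176 with the larger pseudocount (log2 change 1.56). Its call also changed without either 7 d array.

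Plastid-encoded photosynthesis genes were lower as a group at 1 h, with a median log2 change of -0.25 over 47 members, of which 2 passed as lower and 45 did not pass (camera adjusted p = 4.1e-08; adjusted p = 0.811 with an estimated correlation). That median was -0.41 without 1 h replicate 1. The psbB transcript, for a core antenna protein of photosystem II, stood at -1.05 ± 0.21 (adjusted p = 0.0685). That p became 0.0362 with the replicate block, 0.0213 without 7 d replicate 1 and 0.0205 without 7 d replicate 2. Plastid-encoded genes for gene expression, such as the RNA polymerase subunit gene rpoC1 (-0.64 ± 0.16) and the ribosomal protein gene rps4 (-0.65 ± 0.18), had a median of -0.19, and the 22 members did not pass (camera adjusted p = 0.0102; adjusted p = 0.811 with an estimated correlation). That call ended without control replicate 2 (median -0.06, adjusted p = 0.278) and without 1 h replicate 2 (adjusted p = 0.163), and the median was -0.37 without control replicate 1. By fry the adjusted p at 1 h was 0.0384 for touch and calmodulin-like genes, 0.0922 for calmodulin-like proteins, 0.113 for U-box ligases, 0.175 for plastid photosynthesis and 0.348 for plastid gene expression. The 3'/5' signal ratio of the GAPDH control probe sets was 1.24 and 1.26 on the control arrays and 1.46 and 1.46 at 1 h. The ubiquitin ratio went the other way, with 2.88 and 2.22 on the control arrays and 2.08 and 1.90 at 1 h. The actin ratio was 1.307 and 1.319 on the control arrays and 1.310 and 1.403 at 1 h. The actin control Actin_5_r read 350 on 1 h replicate 2 against 139 to 182 on the other arrays.

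**Figure D1:**
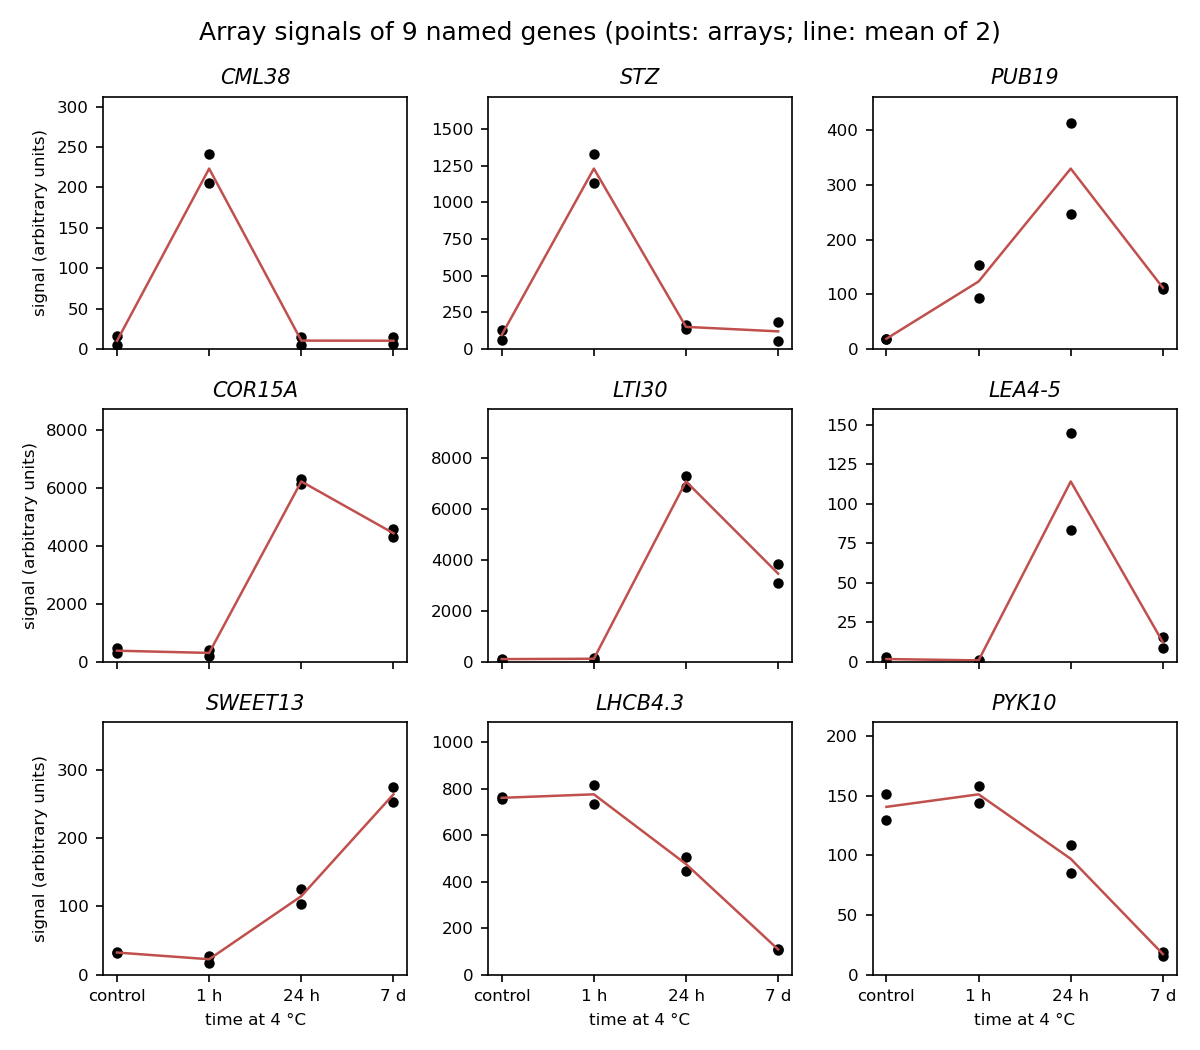
Array signal (arbitrary units, linear axes from 0, a separate scale for each gene) of 9 named genes against time at 4 °C; points are the 2 arrays of each time and the line joins their means. CML38 and STZ were highest at 1 h, COR15A, LTI30 and LEA4-5 at 24 h and SWEET13 at 7 d, while LHCB4.3 and PYK10 were lowest at 7 d.

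After 24 h the cold-regulated genes were among the largest changes. LTI30, a dehydrin, rose 65.8-fold (log2 6.04 ± 0.31, adjusted p = 1.4e-05, n = 2 arrays per time), from a signal of 102 ± 22.7 (SD) to 7063 ± 323. COR15A rose 16.6-fold (4.05 ± 0.29, adjusted p = 6.1e-05), from 380 ± 129 to 6220 ± 135, and its neighbour in function COR15B rose 15.2-fold (3.93 ± 0.32, adjusted p = 0.000124). LEA4-5, a late embryogenesis abundant protein, rose from 1.68 ± 1.42 to 114 ± 43.6 (3.92 ± 0.39, adjusted p = 0.000338). EXPA8, an expansin that loosens cell walls, fell by 3.41 ± 0.43 on the log2 scale (adjusted p = 0.000953).

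In all, 1638 probe sets were higher and 2235 lower than in the control at 24 h, and 752 and 788 of them changed at least 2-fold. Centring each array on its median turned the split to 2051 higher and 1714 lower (54.5% higher against 42.3%). Besides LTI30, the largest rises among named genes were AT1G16850 at 5.73 ± 0.29, AT1G51090 at 5.20 ± 0.29, AT1G68500 at 4.50 ± 0.19, AT3G55580 at 4.34 ± 0.28, AT2G43620 at 4.22 ± 0.26, AT1G48100 at 4.21 ± 0.18 and AT1G11210 at 4.14 ± 0.33 (adjusted p from 4.5e-06 to 9.9e-05). The lowest were AT1G13650 at -3.60 ± 0.42, EXPA8, AT2G34620 at -3.08 ± 0.17, AT4G33666 at -2.66 ± 0.24, AT1G51400 at -2.64 ± 0.15, AT3G04210 at -2.62 ± 0.24, AT5G02230 at -2.62 ± 0.25 and AT3G26510 at -2.60 ± 0.19. All of these genes passed without each array in turn. The count of higher probe sets was 1017 without control replicate 1, 1006 without 24 h replicate 1 and 896 without 24 h replicate 2. That of lower ones was 1099, 1416 and 1052 without the same arrays and 1219 without control replicate 2.

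All 6 tested genes of the list of COR genes and other targets of the CBF transcription factors were higher at 24 h, and 6 when adjusted over the list alone. Their median log2 change was 3.96 (camera adjusted p = 3.8e-07; adjusted p = 0.442 with an estimated correlation). Among genes for late embryogenesis abundant and dehydration-induced proteins, 6 were higher, 1 lower and 2 did not pass, with a median of 0.92 (camera adjusted p = 0.00245; adjusted p = 0.811 with an estimated correlation). They included LEA4-5, the temperature-induced lipocalin TIL (2.19 ± 0.11, adjusted p = 1.4e-05) and AT1G54410 (1.14 ± 0.13, adjusted p = 0.000674). PUB19 stayed high, at 13.2-fold the control (3.72 ± 0.27, adjusted p = 7.4e-05).

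All 6 tested ribosome biogenesis genes, a list fixed beforehand, were higher at 24 h, 6 also when adjusted over the list alone (median 1.304; camera adjusted p = 2.8e-06; adjusted p = 0.442 with an estimated correlation). AT3G05060 rose 2.70-fold (1.43 ± 0.19), AT5G14520 2.44-fold (1.29 ± 0.14) and AT2G40360 2.13-fold (1.09 ± 0.13). Of 98 genes for cytosolic ribosomal proteins, 32 were higher, 2 lower and 64 did not pass (median 0.29; camera adjusted p = 1.8e-09; adjusted p = 0.811 with an estimated correlation). The largest named members were AT5G59240 at 2.36 ± 0.36 and AT1G80750 at 1.38 ± 0.19. By fry the adjusted p was 0.0103 for COR and CBF-target genes, 0.00704 for late embryogenesis abundant and dehydration-induced proteins, 0.00634 for ribosome biogenesis and 0.0828 for cytosolic ribosomal proteins.

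Several chloroplast-related groups had lower medians at 24 h, when the median of all probe sets stood at -0.10. The list medians here are not relative to it. Of 47 plastid-encoded photosynthesis genes, 13 were lower, 1 higher and 33 did not pass, with a median of -0.49 (camera adjusted p = 0.00401; adjusted p = 0.811 with an estimated correlation). Among them psbB fell by 1.49 ± 0.21, psbT by 1.39 ± 0.18 and cemA by 0.76 ± 0.14. Plastid-encoded genes for gene expression had 7 lower and 15 not passing (median -0.49; camera adjusted p = 0.0185; adjusted p = 0.811 with an estimated correlation). Here rpoB stood at -1.03 ± 0.17 and rps2 at -0.80 ± 0.12. Nuclear genes for the assembly of the photosystems and of the NADH dehydrogenase-like (NDH) complex had 6 lower and 12 not passing (median -0.47; camera adjusted p = 0.0102; adjusted p = 0.811 with an estimated correlation). LPA2, an assembly factor of photosystem II, stood at -1.05 ± 0.16. Tetrapyrrole and chlorophyll synthesis had 4 lower and 7 not passing (median -0.39; camera adjusted p = 0.0220; adjusted p = 0.811 with an estimated correlation). They included HEME1, a uroporphyrinogen decarboxylase, at -0.89 ± 0.12, and CHLM, the magnesium protoporphyrin methyltransferase, at -0.73 ± 0.13. Without 24 h replicate 2 the adjusted p was 0.0908 for plastid photosynthesis (median -0.31), 0.178 for plastid gene expression and 0.0908 for tetrapyrrole synthesis. Without control replicate 2 it was 0.0647 for plastid gene expression, and without control replicate 1 it was 0.0528 for photosystem and NDH assembly. Dropping the variance trend ended the tetrapyrrole call (adjusted p = 0.0560). By fry tetrapyrrole synthesis passed (adjusted p = 0.0190), while plastid photosynthesis (0.124), plastid gene expression (0.114) and photosystem and NDH assembly (0.0828) did not.

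Other chloroplast groups did not pass by camera at 24 h. Photosystem and light-harvesting proteins had 2 of 7 lower, also when adjusted over the list alone (camera adjusted p = 0.0824), and nuclear genes for plastid ribosomal proteins 1 of 8 lower (camera adjusted p = 0.331). The 3 Calvin cycle genes did not pass (camera adjusted p = 0.758). By fry the photosystem list passed (adjusted p = 0.0327). The median log2 signal of mitochondrion-encoded probe sets was 4.76 and 4.62 on the 24 h arrays against 5.15 and 5.29 on the control arrays, and that of plastid-encoded photosynthesis genes 10.12 and 9.80 against 10.47 and 10.37. Whether all organelle transcripts were labelled less on the 24 h arrays was not tested.

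**Figure D2:**
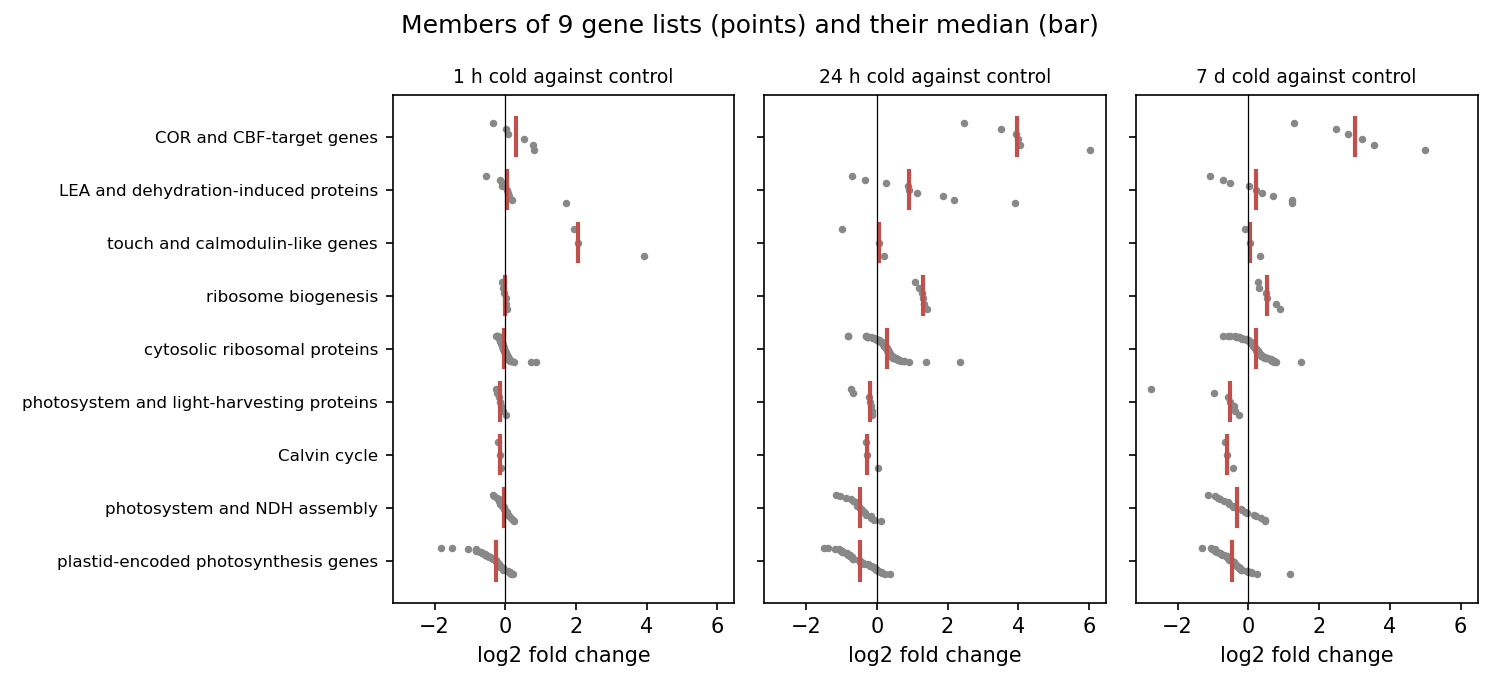
Log2 fold change against control (horizontal axis) of the tested members of 9 gene lists (vertical axis) at 1 h, 24 h and 7 d at 4 °C, in 3 panels; each point is a gene and the bar is the median of its list. The medians of the COR and CBF-target genes were 0.31, 3.96 and 3.02 at the 3 times, and those of the plastid-encoded photosynthesis genes -0.25, -0.49 and -0.46.

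After 7 d the COR genes were still far above the control, and LHCB4.3 was among the lower genes. LTI30 stood 32.0-fold above control (log2 5.00 ± 0.31, adjusted p = 9.8e-05, n = 2 arrays per time) at a signal of 3451 ± 528 (SD). COR15A stood 11.8-fold above it (3.56 ± 0.29, adjusted p = 0.000218) and COR15B 9.37-fold (3.23 ± 0.32, adjusted p = 0.000694). LHCB4.3, which encodes a minor antenna protein of photosystem II, was 6.71-fold lower (-2.75 ± 0.12, adjusted p = 1.2e-05), at 108 ± 2.13 against 761 ± 7.74. The sugar transporter gene SWEET13 rose 7.04-fold (2.82 ± 0.19, adjusted p = 0.000146) and SWEET17, for a fructose carrier of the vacuolar membrane, fell by 2.62 ± 0.34 (adjusted p = 0.00226).

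In all, 1082 probe sets were higher and 1260 lower at 7 d, with 342 and 394 changed at least 2-fold. Other large rises among named genes were AT1G16850 at 4.53 ± 0.29, AT3G55580 at 3.77 ± 0.28, AT2G43620 at 3.77 ± 0.26, AT1G80130 at 3.69 ± 0.35 and AT4G12500 at 3.35 ± 0.25 (adjusted p from 9.96e-05 to 0.000500). The lowest were AT1G13650 at -3.36 ± 0.42, AT4G21870 at -2.94 ± 0.41, AT4G23670 at -2.84 ± 0.26, AT5G40450 at -2.69 ± 0.21 and EXPA8 at -2.60 ± 0.43. MSRB6, a methionine sulfoxide reductase, was 5.59-fold lower (-2.48 ± 0.14, adjusted p = 7.0e-05). These genes passed without each array in turn. The count of higher probe sets was 365 without control replicate 1, 532 without control replicate 2, 527 without 7 d replicate 1 and 548 without 7 d replicate 2. That of lower ones was 416, 637, 758 and 625. A fit of the control and 7 d arrays alone gave 594 higher and 771 lower.

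PYK10, a beta-glucosidase gene known from roots and hypocotyls, fell from a signal of 141 ± 15.2 in the control to 17.2 ± 2.32 at 7 d (-2.66 ± 0.17, adjusted p = 9.96e-05). At 1 h its signal was 151 ± 9.89 and at 24 h 97.2 ± 16.8. The samples were labelled as above-ground tissue, and the other 3 root markers named by the annotation were not tested because of low signals. EXPA18 had mean signals of 24, 17, 8.8 and 6.4 at 0 h, 1 h, 24 h and 7 d, EXPA7 12, 5.9, 8.6 and 6.0, and XTH26 stayed at or below 1.4. Among markers of pollen, egg and seed, SETH5 alone was tested, with 59.5 ± 13.4 in the control and 69.5 ± 18.3 at 7 d.

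Of the 6 COR and CBF-target genes, 5 were higher at 7 d, and 6 when adjusted over the list alone (median 3.02; camera adjusted p = 1.3e-06; adjusted p = 0.442 with an estimated correlation). Ribosome biogenesis genes had 3 of 6 higher, and 4 when adjusted over the list alone (median 0.52; camera adjusted p = 0.00486; adjusted p = 0.506 with an estimated correlation). These were AT3G15460 at 0.90 ± 0.16, AT3G05060 at 0.79 ± 0.19 and AT5G14520 at 0.53 ± 0.14. Without control replicate 1 their adjusted p became 0.0565, 0.0996 and 0.187. Without control replicate 2 AT3G05060 and AT5G14520 had 0.100 and 0.0874, and without 7 d replicate 1 0.100 and 0.184. AT5G14520 also had 0.0600 and 0.0596 without 1 h replicate 1 or 2, and 0.0573 and 0.0565 without 24 h replicate 1 or 2. It had 0.0521 with quantile normalization, 0.0530 with no filter, 0.0740 without the variance trend and 0.0890 with the 2 times alone, where AT3G05060 had 0.0617. Cytosolic ribosomal protein genes had 25 higher, 1 lower and 72 not passing (median 0.21; camera adjusted p = 8.8e-06; adjusted p = 0.811 with an estimated correlation). Among them AT5G58420 stood at 0.74 ± 0.11 (adjusted p = 0.00439). By fry the adjusted p was 0.0157 for COR and CBF-target genes, 0.0327 for ribosome biogenesis and 0.124 for cytosolic ribosomal proteins.

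Of 7 nuclear genes for photosystem and light-harvesting proteins, 5 were lower at 7 d and 7 were lower when adjusted over the list alone (median -0.53; camera adjusted p = 9.2e-06; adjusted p = 0.442 with an estimated correlation). Besides LHCB4.3 they included PSAE-1 at -0.96 ± 0.10 and PSAN at -0.56 ± 0.09, both subunits of photosystem I. All 3 tested Calvin cycle genes were lower, also when adjusted over the list alone (median -0.60; camera adjusted p = 0.00926; adjusted p = 0.506 with an estimated correlation). RCA, the Rubisco activase, stood at -0.67 ± 0.10, PRK, phosphoribulokinase, at -0.60 ± 0.14 and SBPASE, sedoheptulose bisphosphatase, at -0.43 ± 0.12. Without control replicate 1, 7 d replicate 1 or 7 d replicate 2 SBPASE had an adjusted p of 0.199, 0.151 or 0.137, and between 0.0649 and 0.0656 without any 1 array of 1 h or 24 h. PRK had 0.110 without control replicate 1 and 0.108 without 7 d replicate 1. With no filter PRK and SBPASE had 0.0593 and 0.114, and without the variance trend 0.0623 and 0.117. SBPASE also had 0.0577 with quantile normalization and 0.0969 with the 2 times alone.

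Plastid-encoded photosynthesis genes had 14 lower, 1 higher and 32 not passing at 7 d (median -0.46; camera adjusted p = 1.2e-07; adjusted p = 0.811 with an estimated correlation). The median log2 signal of this list was 9.34 on 7 d replicate 1 and 10.10 on 7 d replicate 2, against 10.47 and 10.37 on the control arrays. Nuclear genes for plastid ribosomal proteins had 2 of 8 lower (median -0.34; camera adjusted p = 0.0152; adjusted p = 0.811 with an estimated correlation). Of these AT1G64510 fell by 0.75 ± 0.12. AT3G13120, at -0.37 ± 0.12, had an adjusted p of 0.0705, and 0.0226 with the replicate block. That list's call ended without control replicate 1 (adjusted p = 0.0984), without 7 d replicate 2 (adjusted p = 0.121) and without the variance trend (adjusted p = 0.0542). By fry the adjusted p was 0.00634 for photosystem and light-harvesting proteins and 0.0230 for the Calvin cycle, but 0.105 for plastid photosynthesis and 0.141 for plastid ribosomal proteins. Other chloroplast groups did not pass by camera at 7 d. Photosystem and NDH assembly had 7 of 18 lower and 11 not passing (camera adjusted p = 0.0794), and tetrapyrrole and chlorophyll synthesis 3 of 11 lower (camera adjusted p = 0.231). Plastid-encoded genes for gene expression had 1 of 22 lower, with a median of -0.13 (camera adjusted p = 0.445). The median log2 signal of mitochondrion-encoded probe sets was 5.14 and 5.02 on the 7 d arrays against 5.15 and 5.29 on the control arrays.

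**Figure D3:**
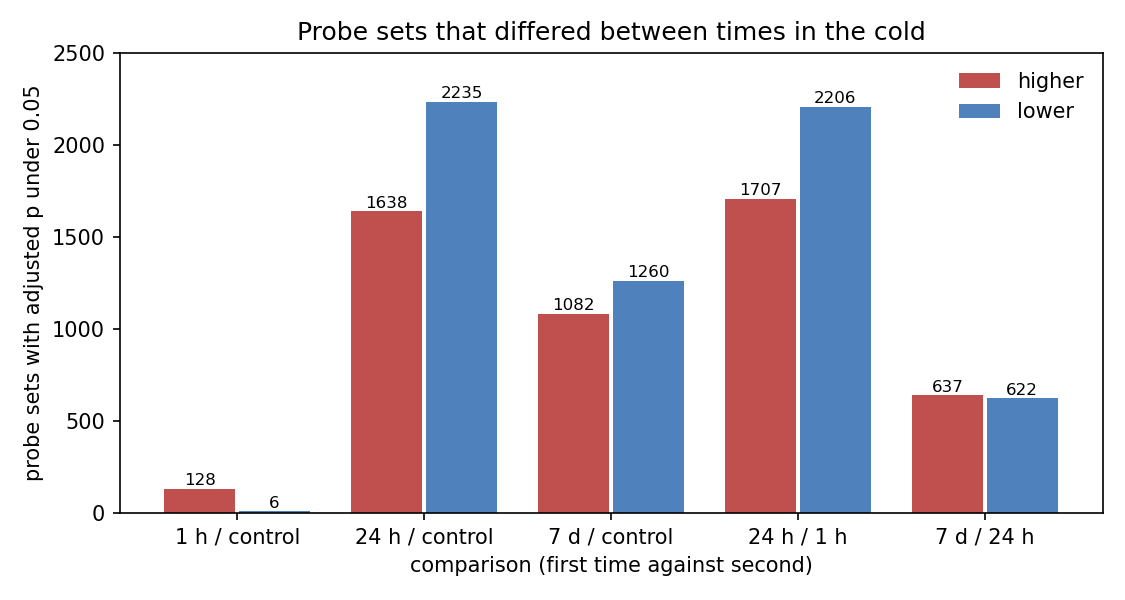
Number of probe sets with an adjusted p under 0.05 (vertical axis) in each comparison (horizontal axis, first time against second), higher in red and lower in blue, out of 14756 tested. The counts were 128 and 6 at 1 h, 1638 and 2235 at 24 h, and 1082 and 1260 at 7 d against control.

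Between 1 h and 24 h several early genes fell while COR genes rose. CML38 dropped by 3.88 ± 0.44 on the log2 scale (adjusted p = 0.000522, n = 2 arrays per time), to a signal of 10.2 ± 6.80 (SD). AT4G29780, AT2G41640, AT1G33760 and AT2G27080 stood at -4.32 ± 0.39, -4.05 ± 0.50, -3.94 ± 0.45 and -3.74 ± 0.36. LTI30 rose by 5.96 ± 0.31 (adjusted p = 1.8e-05), AT1G16850 by 5.66 ± 0.29, AT3G55580 by 4.62 ± 0.28, COR15A by 4.40 ± 0.29 (adjusted p = 4.3e-05) and AT1G68500 by 4.13 ± 0.19. Of the 128 probe sets higher at 1 h than in the control, 33 were also higher than the control at 24 h and 15 were lower than it. Against the control PUB19 stood at 2.35 at 1 h and 3.72 at 24 h. All 10 named calls between these times passed without each array in turn.

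In this comparison 1707 probe sets were higher and 2206 lower at 24 h, and 703 and 931 changed at least 2-fold. Centring on array medians gave 2303 higher and 1683 lower (57.8% higher against 43.6%) and moved the median of all probe sets by 0.11. List medians are therefore given here relative to the median of all, -0.07. The relative median was 3.76 for COR and CBF-target genes (6 of 6 higher, 6 adjusted over the list alone; camera adjusted p = 1.3e-06; adjusted p = 0.442 with an estimated correlation). It was 1.38 for ribosome biogenesis (6 of 6 higher, 6 adjusted over the list alone; camera adjusted p = 4.1e-06; adjusted p = 0.442 with an estimated correlation). Cytosolic ribosomal proteins stood at 0.39 (39 of 98 higher; camera adjusted p = 3.3e-10; adjusted p = 0.811 with an estimated correlation). Late embryogenesis abundant and dehydration-induced proteins stood at 1.14 (6 higher, 2 lower; camera adjusted p = 0.0152; adjusted p = 0.811 with an estimated correlation). Touch and calmodulin-like genes stood at -2.95 (3 of 3 lower, 3 adjusted over the list alone; camera adjusted p = 0.0277; adjusted p = 0.529 with an estimated correlation) and calmodulin-like proteins at -1.66 (5 of 7 lower; camera adjusted p = 0.00780; adjusted p = 0.811 with an estimated correlation). Photosystem and NDH assembly stood at -0.45 (6 of 18 lower; camera adjusted p = 0.0152; adjusted p = 0.811 with an estimated correlation). The touch list's call ended without 24 h replicate 1 (adjusted p = 0.0646) and with a smaller pseudocount (adjusted p = 0.0514), and that of calmodulin-like proteins with the 60th percentile filter (adjusted p = 0.0543). The call of photosystem and NDH assembly ended without 1 h replicate 1 (adjusted p = 0.0815) or 24 h replicate 2 (adjusted p = 0.0520). By fry cytosolic ribosomal proteins (adjusted p = 0.0663) and photosystem and NDH assembly (0.104) did not pass, and the other 5 lists did, with adjusted p from 0.00634 to 0.0351. The count of higher probe sets was 973 without 1 h replicate 1, 1119 without 1 h replicate 2, 967 without 24 h replicate 1 and 914 without 24 h replicate 2. That of lower ones was 994, 1257, 1379 and 1176.

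Between 24 h and 7 d several of the genes most induced at 24 h declined. The median of all probe sets stood at 0.08, and centring on array medians moved it by -0.11, so changes are given relative to it. LEA4-5 stood at -2.76 (-2.69 ± 0.39 before that adjustment, adjusted p = 0.00732, n = 2 arrays per time), the expansin-like EXLA1 at -2.85 (-2.77 ± 0.24, adjusted p = 0.00117), AT1G20030 at -3.73, AT1G51090 at -2.98 and AT1G48100 at -2.68. Higher at 7 d than at 24 h were AT3G04210 at 2.42, AT1G52000 at 2.38, AT3G53980 at 2.21, AT3G14395 at 2.198 and AT3G15550 at 2.04, on the same relative scale. AT3G53980, AT3G14395 and AT3G15550 missed the threshold without 24 h replicate 1 (adjusted p = 0.150, 0.0897 and 0.0615), 24 h replicate 2 (0.0999, 0.118 and 0.0743), 7 d replicate 1 (0.0992, 0.0589 and 0.0562) or 7 d replicate 2 (0.123, 0.138 and 0.0928). LEA4-5 missed it without 24 h replicate 2 (0.0810). AT3G53980 also missed it after quantile normalization (0.0507), with the smaller pseudocount (0.0672), with no filter (0.0613) and without the variance trend (0.0532).

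Here 637 probe sets were higher and 622 lower at 7 d, with 208 and 232 changed at least 2-fold. Centring on array medians gave 401 higher and 1030 lower (28.0% higher against 50.6%), quantile normalization 404 and 580, and the replicate block 1388 and 1093. There were 134 higher and 142 lower without 24 h replicate 1, and 101 and 135 without 24 h replicate 2. There were 127 and 200 without 7 d replicate 2, and 381 higher without 7 d replicate 1. No filter on low values gave 342 higher, the arrays of the 2 times alone 327, and a fit without the variance trend 409 higher and 402 lower.

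Relative to the median of all probe sets, ribosome biogenesis genes stood at -0.86 at 7 d against 24 h (4 of 6 lower, 5 adjusted over the list alone; camera adjusted p = 2.1e-05; adjusted p = 0.442 with an estimated correlation). Late embryogenesis abundant and dehydration-induced proteins stood at -0.86 (5 of 9 lower; camera adjusted p = 7.5e-06; adjusted p = 0.811 with an estimated correlation). Flavonoid and anthocyanin synthesis stood at -0.82 (1 of 6 lower, 3 adjusted over the list alone; camera adjusted p = 0.00562; adjusted p = 0.534 with an estimated correlation). COR and CBF-target genes stood at -0.95 (1 of 6 lower, 2 adjusted over the list alone; camera adjusted p = 0.00394; adjusted p = 0.564 with an estimated correlation), a call that quantile normalization ended (adjusted p = 0.118). Photosystem and light-harvesting proteins stood at -0.43 (3 of 7 lower; adjusted over the list alone, 5 lower and 1 higher; camera adjusted p = 0.000602; adjusted p = 0.442 with an estimated correlation), but their median turned to 0.06 after quantile normalization (adjusted p = 0.824). Calvin cycle genes stood at -0.36 (1 of 3 lower, 1 adjusted over the list alone; camera adjusted p = 0.0249; adjusted p = 0.519 with an estimated correlation), and that call ended after quantile normalization (adjusted p = 0.774), without the variance trend (adjusted p = 0.0718), without 24 h replicate 1 (median -0.16 against -0.29, neither relative, adjusted p = 0.0805) and without 7 d replicate 1 (adjusted p = 0.108). Cytosolic ribosomal proteins lay at the threshold (camera adjusted p = 0.049998; adjusted p = 0.846 with an estimated correlation), with 1 of 98 lower and a relative median of -0.12. The replicate block ended that call (adjusted p = 0.0586), as did the larger pseudocount (0.0519), the 60th percentile filter (0.103), a fit without the variance trend (0.0739) and the mean over a gene's probe sets (0.0507). Before subtraction the median was -0.040, but -0.025 without 24 h replicate 1 and -0.096 without 7 d replicate 1. Quantile normalization turned its direction (median 0.12, adjusted p = 0.0395), as did leaving out 7 d replicate 2 (median 0.03, adjusted p = 0.547). It also ended without control replicate 1 (0.0501), 1 h replicate 1 (0.0601), 1 h replicate 2 (0.0546), 24 h replicate 1 (0.0713) and 24 h replicate 2 (0.0908). By fry the adjusted p was 0.293 for COR and CBF-target genes, 0.184 for flavonoid synthesis, 0.0577 for the Calvin cycle and 0.603 for cytosolic ribosomal proteins. It was 0.0175 for ribosome biogenesis, 0.0102 for late embryogenesis abundant proteins and 0.0103 for photosystem proteins.

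The responses at 24 h and 7 d shared many probe sets. Of 1638 higher at 24 h and 1082 higher at 7 d, 682 were the same, against 120 for independent lists of those sizes. Of 2235 and 1260 lower, 817 were the same, against 191. Of the 128 higher at 1 h, 33 were also higher at 24 h (14.2 for independent lists) and 15 lower, and 19 were higher at 7 d (9.39) and 5 lower. These comparisons use the same control arrays, so their lists are not independent and the numbers for independent lists are no test. Across probe sets, which are not independent replicates, the log2 changes at 24 h and 7 d correlated with r = 0.73. Those at 1 h correlated with r = 0.18 (24 h) and 0.19 (7 d), where unchanged groups simulated against the same controls gave 0.50 in each case. That 0.50 is set by the shared controls alone, and changes present at only 1 of the times lower r. An r under 0.50 therefore does not show less sharing than among unchanged groups. The covariance was above the simulated one by 0.25 for 24 h and 7 d, 0.0157 for 1 h and 24 h, and 0.00972 for 1 h and 7 d. The simulation held no effect shared by arrays of the same replicate number. In a comparison added after the results were seen, each time was read on 1 replicate against the control array of the same number, so that the 2 changes shared no array. The correlation of 24 h with 7 d was then 0.53 and 0.58 in the 2 ways of splitting (covariance 0.23 and 0.26). That of 1 h with 24 h was 0.016 and 0.13 (covariance 0.00540 and 0.0354), and that of 1 h with 7 d was 0.065 both ways (covariance 0.0177 and 0.0153). The correlation of 1 h with 24 h was 0.25 without control replicate 1 and 0.30 without control replicate 2, and that of 1 h with 7 d was 0.36 without control replicate 2 and 0.10 without 7 d replicate 2. That of 24 h with 7 d stayed between 0.64 and 0.75 without any 1 array.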

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

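The test of mitochondrion-encoded probe sets was chosen after the fall of plastid transcripts had been seen, and the tests with lists matched on signal were written after the camera calls but before the matched lists were drawn.

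These results differed between times in the cold, by a test of the difference itself with 2 arrays per time. Changes in this paragraph and the next are not relative to the median of all probe sets. That median was -0.07 between 1 h and 24 h and 0.08 between 24 h and 7 d. The list differences passed camera at its preset correlation, but not with an estimated correlation, where their adjusted p ranged from 0.442 to 0.846. Between 1 h and 24 h the median log2 change was 3.69 for COR and CBF-target genes, -3.02 for touch and calmodulin-like genes, 1.31 for ribosome biogenesis and 0.32 for cytosolic ribosomal proteins. It was -1.73 for calmodulin-like proteins, 1.07 for late embryogenesis abundant and dehydration-induced proteins, and -0.52 for photosystem and NDH assembly. Single genes that rose over the same interval were LTI30 (5.96), AT1G16850 (5.66), AT3G55580 (4.62), COR15A (4.40) and AT1G68500 (4.13). Those that fell were AT4G29780 (-4.32), AT2G41640 (-4.05), AT1G33760 (-3.94), CML38 (-3.88) and AT2G27080 (-3.74).

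Between 24 h and 7 d the median was -0.87 for COR and CBF-target genes, -0.78 for ribosome biogenesis, -0.78 for late embryogenesis abundant and dehydration-induced proteins, and -0.74 for flavonoid and anthocyanin synthesis. It was -0.35 for photosystem and light-harvesting proteins, -0.29 for the Calvin cycle and -0.040 for cytosolic ribosomal proteins. Quantile normalization turned the medians of photosystem proteins to 0.055 and of cytosolic ribosomal proteins to 0.12, so neither had a settled direction. With an estimated correlation the adjusted p was 0.564 for COR and CBF-target genes and 0.519 for the Calvin cycle, and quantile normalization ended both calls (adjusted p = 0.118 and 0.774). Genes lower at 7 d were AT1G20030 (-3.66), AT1G51090 (-2.90), EXLA1 (-2.77), LEA4-5 (-2.69) and AT1G48100 (-2.60). Genes higher were AT3G04210 (2.50), AT1G52000 (2.45), AT3G53980 (2.28), AT3G14395 (2.27) and AT3G15550 (2.11).

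At 1 h 2 of 47 plastid-encoded photosynthesis genes passed as lower, and the list passed camera at its preset correlation. With an estimated one, where camera had little power, it did not (adjusted p = 0.811). It also did not pass by fry (adjusted p = 0.175), so the fall of the group is itself unsettled. The lower level may have a technical source, since 13 mitochondrion-encoded probe sets had a median of -0.26 and 10 of them were lower. Less labelling of all organelle transcripts on the 1 h arrays therefore stays open, although the mitochondrial signals were weak (mean log2 signal of 4.88, against 10.06 for the plastid genes). A bias that follows signal strength was argued against, since 0% of 10000 lists matched on mean signal had a median as low as -0.25. The central part of their medians, with both tails left out, ran from -0.12 to -0.04. For a single deviating array, the pairs of arrays with the same number gave medians of -0.24 and -0.39, each with 37 of 47 genes below 0. Those pairs alone cannot decide the question, since no label states the pairing. Leaving out each array in turn, which needs no pairing, kept the median of the list at 1 h below 0. Its direction therefore did not rest on 1 array, but the level of the list differed between the 1 h arrays. The median log2 signal of the list was 10.47 and 10.37 on the control arrays. It was 10.35 on 1 h replicate 1, close to the second control array, and 9.86 on 1 h replicate 2. Time in the cold was the only group in the design, and no biological explanation was tested.

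Of 98 cytosolic ribosomal proteins, 32 were higher at 24 h, 2 lower and 64 did not pass, with a median of 0.29. The list passed camera at its preset correlation. With an estimated one, where camera had little power, it did not (adjusted p = 0.811). It also did not pass by fry (adjusted p = 0.0828), so the rise of the group is itself unsettled. For it 2 technical explanations were tested. A bias that follows signal strength was argued against, since 0% of 10000 lists matched on mean signal had a median as high. The central part of their medians, with both tails left out, ran from -0.15 to 0.05. Scaling of the 24 h arrays was argued against as the whole cause, because quantile normalization left a median of 0.18 with 72 of 98 genes above 0. The SE of that median, 0.02, was taken over the genes, which are not independent replicates, and measures no spread between arrays. Other technical sources were not tested, so these 2 results do not tie any rise to the cold. That it belongs to the cold treatment remains a hypothesis, found and tested on the same arrays. The drop in light and the age of the plants stay open as well.

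For the calmodulin-like and touch genes higher at 1 h, moving the plants or the drop in light rather than cold cannot be told apart from the cold itself. The series has 0 arrays of plants moved or dimmed without cold. No biological explanation was tested.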

How the results depend on the processing

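The fit of the 2 times alone for single genes, the correlations without 1 array and those with separate control arrays were added after the data were seen, and the other alternatives given here were planned. For the 171 pairs of a named gene and a comparison, the 9 alternatives other than leaving out an array kept direction and side of the threshold in 1479 of 1528 values, with 44 weaker, 5 stronger and 0 reversed. The 2-fold minimum was not applied to single genes. Leaving out 1 array kept 1178 of 1368, with 184 weaker, 4 stronger and 2 reversed; the lone array left at a time is assumed to vary like the others. The 2 reversed were COR15A at 1 h, which had not passed: 0.00 without control replicate 1 and 0.10 without 1 h replicate 2, in a range from -0.79 to 0.10.

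Of the 34 list calls, 0 passed camera with an estimated correlation (7 of 150 tests had an unadjusted p under 0.05) and 17 passed fry. Leaving out 1 array gave 31 to 39 calls. Between 7 d and 24 h, quantile normalization reversed the medians of photosystem and light-harvesting proteins (0.055) and of cytosolic ribosomal proteins (0.12), and the latter was also reversed without 7 d replicate 2 (0.028; range -0.096 to 0.028). The cause was not tested.

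Requiring a 2-fold change gave, by its construction, 752 higher and 788 lower at 24 h, 342 and 394 at 7 d, 703 and 931 between 1 h and 24 h, 208 and 232 between 24 h and 7 d, and 1849 between any times. The 2 times alone, with fewer arrays, gave 2 lower at 1 h, 594 higher and 771 lower at 7 d, and 327 higher between 24 h and 7 d. For that last comparison quantile normalization gave 404 higher, median-centred values 401 and 1030, no filter 342 higher (more probe sets tested), and no variance trend 409 and 402. The replicate block gave 215 higher at 1 h, and 1388 and 1093 between 24 h and 7 d; elsewhere it changed no call not given in the report. The cause was not tested.

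Leaving out each array in turn gave 34 to 157 higher and 0 to 5 lower at 1 h (0 by limma without control replicate 2 or 1 h replicate 2, with 432 and 292 at an unadjusted p under 0.05). It gave 896 to 1646 and 1052 to 2329 at 24 h, and 365 to 915 and 416 to 1076 at 7 d. Between 1 h and 24 h it gave 914 to 1713 and 994 to 2293, and between 24 h and 7 d 101 to 485 and 135 to 594. Any difference between times held for 2543 to 3815 probe sets. The correlation of 1 h with 24 h ranged from 0.15 to 0.30, of 1 h with 7 d from 0.10 to 0.36, and of 24 h with 7 d from 0.64 to 0.75; without the filter they were 0.25, 0.29 and 0.69. With separate control arrays, in 2 ways, they were 0.016 and 0.13, 0.065 and 0.065, and 0.53 and 0.58. Near background the pseudocount of 6.07 compresses fold changes.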

Other observations

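The test of whether the 7 d response is a reduced 24 h response was chosen after the results had been seen.

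At 24 h sugar carriers and wall proteins moved in both directions, and their lists did not pass camera at 24 h or 7 d. By fry the SWEET list passed at 24 h and 7 d (adjusted p = 0.00704 and 0.00651), as did the expansins fixed beforehand (0.0157 and 0.0230). SWEET13 rose 3.14-fold at 24 h (log2 1.65 ± 0.19, adjusted p = 0.000725), SWEET4 rose by 1.51 ± 0.20 and SWEET1 by 1.51 ± 0.12, and at 7 d SWEET4 stood at 2.09 ± 0.20 and SWEET1 at 0.95 ± 0.12. Of the 9 genes for SWEET and tonoplast sugar carriers, 4 were higher and 2 lower at 24 h, with a median of -0.04 but a mean of 0.33 (camera adjusted p = 0.288). At 7 d the same counts held, 4 and 2 (camera adjusted p = 0.308). Of 15 genes for xyloglucan-modifying enzymes and expansins, 2 were higher and 5 lower at 24 h (camera adjusted p = 0.614): EXLA1 rose 5.17-fold (2.37 ± 0.24), while EXPB3 stood at -1.40 ± 0.18. In the list of expansins and wall-loosening enzymes fixed beforehand, 2 of 3 were lower at 24 h and at 7 d, also when adjusted over the list alone (camera adjusted p = 0.216 and 0.144).

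Several families of conjugating and redox enzymes had members going each way at 24 h. Among all 14756 tested probe sets 1638 were higher and 2235 lower at that time, so such a mix is not by itself a trait of a family. Among 26 UDP-glycosyltransferases 4 were higher and 5 lower (camera adjusted p = 0.360), with UGT78D3 at 2.70 ± 0.45, UGT72B3 at 2.04 ± 0.22 and UGT84A3 at 1.70 ± 0.28. Flavonoid and anthocyanin synthesis had 2 of 6 higher and 1 lower, as when adjusted over the list alone (camera adjusted p = 0.758), and the flavonol glucosyltransferase gene UGT78D2 rose 2.48-fold (1.31 ± 0.23). Of 7 glutathione transferases 1 was higher and 3 lower (camera adjusted p = 0.480, fry adjusted p = 0.0208), and GSTU18 stood at -1.89 ± 0.17 and GSTU27 at -1.65 ± 0.21. For ascorbate and redox 3 of 15 were higher and 4 lower (camera adjusted p = 0.780), among them GME, which makes GDP-L-galactose for ascorbate, at 0.93 ± 0.13 and the monodehydroascorbate reductase ATMDAR2 at -1.05 ± 0.18. The auxin-response gene IAA29 rose 4.33-fold (2.11 ± 0.40), as 1 of 3 higher in a list of 9 (camera adjusted p = 0.132). In the lists fixed beforehand, the 3 tested genes for starch breakdown and sugar synthesis did not pass at 24 h, with log2 changes from -0.80 to -0.06 (camera adjusted p = 0.870), and 1 of 3 cell division genes was lower, also when adjusted over the list alone (camera adjusted p = 0.874).

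Whether the 7 d response is a reduced 24 h response was asked with 500 probe sets per direction, chosen on 1 replicate and read on the other. Chosen at 24 h, they had a ratio of the median change at 7 d to that at 24 h from 0.502 to 0.602 in the 4 readings. Choosing at a time favours probe sets that change more at that time, so these ratios decide nothing alone. Chosen at 7 d, the higher probe sets had ratios of 0.832 ± 0.041 (SE) and 1.05 ± 0.07, and the lower ones 1.11 ± 0.05 and 1.19 ± 0.06. These SEs were taken over the probe sets, which are not independent replicates, and not over arrays. The question therefore stayed open. SWEET13 (1.65 at 24 h and 2.82 at 7 d) and LHCB4.3 (-0.67 and -2.75) lay further from the control at 7 d. Both are among the genes with large changes at 7 d, a choice that favours this pattern, so they do not bear on the question.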
